A study of Mus musculus with 12 samples.

How the data were processed

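Gene expression was measured in mouse bone marrow-derived dendritic cells (BMDCs), cells grown from the marrow of female mice with GM-CSF, a growth factor that drives marrow progenitors towards dendritic cells. Per the labels, the loosely adherent and non-adherent cells of the culture were taken as immature dendritic cells and then exposed for 6 h to 300 µg/ml γ-PGA nanoparticles, to 1 µg/ml LPS (lipopolysaccharide), to 300 µg/ml γ-PGA not formed into particles (unparticulate γ-PGA), or to PBS (phosphate-buffered saline, the control). γ-PGA is poly(γ-glutamic acid), a polymer of glutamate made by some bacilli. Each of the 4 groups had 3 arrays, from experiments that the labels call independent. Groups were taken from the array titles, because the free-text description names PBS treatment for every array. RNA was labelled with Cy3 and hybridised to 1-colour Agilent mouse oligonucleotide arrays, and the images were read with Agilent Feature Extraction 9.1.3.1, per the file headers.

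The scanner values are linear spot intensities after background subtraction by Feature Extraction, per the file headers. Each array held 45018 spots, of which 43379 were not controls, for 41174 different probes. The 75th percentile of the spot intensity ran from 339 to 472 over the arrays, 50.9% to 59.6% of the non-control spots were well above background, and 165 to 223 spots were saturated. The number of arrays limits the precision. The authors' processed value table holds linear ratios. Set against the scanner values, its values behaved like array-scaled intensities of each probe divided by the median of the 3 PBS arrays, with r of at least 0.996 and a median absolute log2 difference of at most 0.0189 over 10066 bright probes. The scale and centring are inferred from the values, since the steps behind the table are not given in the sources used here. Its column medians were 0.985, 1.00 and 1.02 for PBS replicates 1 to 3, 1.06, 1.07 and 1.31 for nanoparticles, 1.04, 1.19 and 0.870 for LPS, and 0.908, 0.936 and 0.959 for unparticulate γ-PGA. It holds 41252 probes, 78 of them not matched to the scanner values.

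Processed intensities were taken to log2 and scaled by subtracting each array's 75th percentile over non-control spots. Control spots and spots marked as non-uniformity or population outliers were left out, and the spots of a probe were averaged. Probes were named through the accession in the scanner values and a RefSeq gene table of assembly GRCm38.p6, used for names only. This named 22951 probes with 16358 symbols, and 22940 of 25422 probes with a RefSeq mRNA accession matched. The others kept their accession or probe name. No coordinates are given, since no genome was used. A probe was tested where it was well above background on all 3 arrays of at least 1 group, with 1 probe per gene, the brightest of those not saturated on any array, or the brightest of all where every probe was saturated on some array. This left 18404 genes, 11578 of them with a symbol. Probes of 1 gene were called in opposite directions for 249, 291, 7, 46, 288 and 288 of 4151 genes with several probes, in the order of the comparisons given next, and at 2-fold or more for 6, 5, 1, 0, 8 and 4.

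The comparisons were nanoparticles, LPS and unparticulate γ-PGA each against PBS, nanoparticles against LPS, and nanoparticles and LPS each against unparticulate γ-PGA. All 12 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 8 residual degrees of freedom), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p-values are from limma, and errors of log2 fold changes are standard errors (SE). Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. Counts of list members were also made with p-values adjusted over the list alone. A gene not well above background, or saturated, on all 3 arrays of a group has only a bound there. Its fold is given as at least N-fold, the bright group's mean over its 3 arrays against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own. The R package data.table (version 1.17.8) was used to read the arrays and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

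The 30 lists covered inflammatory cytokines, chemokines, chemokine receptors, costimulation and maturation, the MHC class I and class II pathways, Toll-like receptors and adaptors, NF-κB and its feedback, the interferon response, inflammatory effectors, cell death and inflammasomes, oxidative stress (NRF2), endoplasmic reticulum and amino acid stress, endocytosis and scavenger receptors, lysosome, cholesterol synthesis, cholesterol efflux (LXR), glycolysis and hypoxia, cell cycle and ribosomal proteins. Markers of dendritic cells and of other cells a marrow culture can hold made up the others: macrophages, neutrophils and progenitors, B cells, T and NK cells, mast cells and basophils, eosinophils, plasmacytoid dendritic cells, erythroid cells, and stroma and osteoclasts. The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule named 16 fixed genes in each comparison against PBS, 2 of which are not analysed here. It added, per list and comparison, up to 4 members with the greatest change among those called, or the member with the smallest p where none was. It added the 5 greatest rises and falls per comparison among called genes whose 3 arrays of one group all lay beyond the 3 of the other, skipping clone, accession and predicted names. For nanoparticles against LPS it also took the 5 greatest rises over PBS after each stimulus among genes that differed in that direction between the stimuli.

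The arrays lay on 3 slides. Slide 1 held the 3 PBS arrays and nanoparticle replicate 3, slide 2 held nanoparticle replicates 1 and 2 with LPS replicates 1 and 2, and slide 3 held LPS replicate 3 and the 3 unparticulate γ-PGA arrays. Slide was fitted as a block (6 residual degrees of freedom), and differences were also taken within slide 1 for nanoparticles against PBS, within slide 2 for nanoparticles against LPS and within slide 3 for LPS against unparticulate γ-PGA. The other 3 comparisons share no slide. Slide 1 gives 1 nanoparticle array against 3 PBS arrays and slide 3 gives 1 LPS array against 3, so the spread there comes from the group of 3 and the lone array is assumed to vary like it. In these 3 comparisons the difference fitted with the block is the difference within the slide, so they are not separate checks. Other alternatives were normexp background correction with an offset of 50, run on the median spot signal in place of the planned mean signal, quantile normalization, scaling to the median, the authors' value table, no filter on dim probes, probes well above background on all 12 arrays only, outlier-marked spots kept, the mean of a gene's probes, eBayes with a trend and robust, a 2-fold minimum, only the 6 arrays compared, the replicate number as a block, limma's fry for lists, and leaving out each array in turn. Masking a part of nanoparticle replicate 1 with uneven spots was added after the data were seen, as were the slide block and the fit without that array for the lists. On values simulated for nanoparticles against PBS over 18404 genes, 70.6%, 81.2% and 95.6% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. So were 44.2% of those given the smallest change simulated, which was under 1.5-fold, and 5.30% of the calls were false. Each set had 200 changed genes and no slide effect, so these shares need not hold for the arrays. Slide shifts with an SD of 0.3 on the log2 scale were also simulated. Unparticulate γ-PGA against PBS then gave a median of 5651.5 false calls without the block and 0 with it. The size of that shift was set, not estimated. Results for some genes that the rule names are not reported here.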

Results

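The arrays compared what γ-PGA nanoparticles, LPS and unparticulate γ-PGA each changed in dendritic cells grown from mouse marrow within 6 h. LPS is the bacterial cell wall component sensed through Toll-like receptor 4 (TLR4), and the unparticulate polymer was given at the same 300 µg/ml as the particles. Each group held 3 arrays, and each fold change is a mean over 3 arrays against a mean over 3 arrays unless stated. Across the genes tested, which are not independent replicates, arrays of 1 group correlated with r of 0.988 to 0.997. The PBS and LPS arrays correlated at 0.907 to 0.912, and the median SD within groups was 0.0906 on the log2 scale. Of 18404 genes, 15732 differed among the 4 groups and 7330 did so with a change of at least 2-fold.

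Nanoparticles raised the classical inflammatory genes strongly. Tnf, which encodes the cytokine TNF-α, rose 62.2-fold (log2 5.96, SE 0.035, adjusted p = 4.96e-14). Il6 rose at least 671-fold, Il1b at least 17.3-fold and Il10, an anti-inflammatory cytokine, at least 51.0-fold. Csf2, which encodes GM-CSF, rose at least 169-fold, Il1a 455-fold (log2 8.83, SE 0.066) and Il23a, a subunit of interleukin 23, at least 57.3-fold. All 19 cytokines measured rose, with a median log2 fold change of 5.50 (adjusted p = 1.01e-11), and 19 of 20 chemokines rose, with a median of 1.90 (adjusted p = 7.2e-10). The neutrophil attractants Cxcl1 and Cxcl2 rose 758-fold (log2 9.57, SE 0.075) and 163-fold (log2 7.35, SE 0.042), Ccl3 at least 20.8-fold and Ccl5 at least 15.5-fold.

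Genes of dendritic cell maturation rose with them. Of 18 costimulation and maturation genes 17 rose and 1 fell (median 2.41, or 2.29 with genes that have only a bound set at it, adjusted p = 6.77e-09). Cd80 and Cd86, ligands of CD28 on T cells, rose 7.45-fold (log2 2.90, SE 0.064) and 2.83-fold (log2 1.5, SE 0.049), and Cd200 rose 23.4-fold. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose 5.42-fold (log2 2.44, SE 0.059), whereas Ccr2 fell by 4.61 on the log2 scale and Ccr6 by 4.03. Among 12 chemokine receptors 2 rose and 7 fell (median −1.33, adjusted p = 0.0787, and 0.0358 without nanoparticle replicate 1). All 24 NF-κB and feedback genes rose (median 2.16, or 2.10 at the bounds, adjusted p = 9.3e-12), among them the feedback inhibitor Socs3 by 65.1-fold and the NF-κB cofactor Nfkbiz by 31-fold. Of 22 inflammatory effectors 20 rose and 1 fell (median 2.97, adjusted p = 3.34e-10). Ptgs2, the inducible prostaglandin synthase, rose at least 1020-fold, the acute phase gene Saa3 147-fold and Nos2, the inducible nitric oxide synthase, at least 13.1-fold. Of 36 interferon response genes 33 rose and 2 fell (median 1.18, adjusted p = 2.96e-11). Gbp5, a guanylate-binding protein, rose 15.0-fold, the antiviral gene Rsad2 11.8-fold, Ifnb1, which encodes interferon β, 8.56-fold (log2 3.1, SE 0.052) and the chemokine gene Cxcl10 1.93-fold (log2 0.95, SE 0.042).

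Metabolic and stress genes also moved after nanoparticles. Of 22 cholesterol synthesis genes 19 rose and 3 fell (median 1.81, adjusted p = 4.13e-07). Hsd17b7, a sterol reductase, rose 12.7-fold (log2 3.67, SE 0.035), Hmgcs1, the synthase that makes HMG-CoA, 5.94-fold and Fdft1, the squalene synthase, 5.59-fold. In the oxidative stress (NRF2) list 20 of 21 genes rose (median 1.33, adjusted p = 2.74e-08), with the cystine transporter Slc7a11 up 11.9-fold, Nqo1 6.35-fold and the heme oxygenase Hmox1 5.63-fold. Of 23 endoplasmic reticulum and amino acid stress genes 19 rose and 3 fell (median 0.64, adjusted p = 8.43e-05), with the heat shock gene Hspa1a up 14.6-fold. Of 29 cell cycle genes 27 fell and 1 rose (median −1.27, adjusted p = 4.18e-09). Ccnd1, which encodes cyclin D1, fell 5.55-fold (log2 −2.47, SE 0.044) and the thymidine kinase gene Tk1 4.69-fold.

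Smaller shifts passed the list test only at the preset correlation. In the MHC class I pathway 12 of 13 genes rose (median 0.44, adjusted p = 0.00179), including the proteasome activator Psme1 by 1.63-fold and the peptide transporter Tap1 by 1.57-fold. Its adjusted p = 0.0915 with an estimated correlation, and 0.0646 under quantile normalization. Toll-like receptors and adaptors had 16 of 25 genes higher and 5 lower (median 0.41, adjusted p = 0.0078, and adjusted p = 0.175 with an estimated correlation). Tlr1 rose 5.63-fold and Tlr8 fell 5.83-fold. Cell death and inflammasome genes had 14 of 22 higher and 6 lower (median 0.61, adjusted p = 0.0085, and adjusted p = 0.0915 with an estimated correlation), with the survival genes Cflar and Bcl2l1 up 9.05-fold and 8.16-fold. Glycolysis and hypoxia genes had 17 of 23 higher and 4 lower (median 0.27, adjusted p = 0.00782, adjusted p = 0.271 with an estimated correlation, and 0.103 under quantile normalization), with the glucose transporter Slc2a1 up 3.51-fold.

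Markers of other cell types moved as well. Of 13 macrophage markers 10 fell and 3 rose (median −1.51, or −1.41 at the bounds, adjusted p = 0.0047, and adjusted p = 0.115 with an estimated correlation). The complement gene C1qa fell 4.80-fold (log2 −2.26, SE 0.033). Of 14 neutrophil and progenitor markers 10 fell and 3 rose (median −0.58, adjusted p = 0.0206, and adjusted p = 0.271 with an estimated correlation), with Retnlg down 3.93-fold. The dendritic cell markers gave 6 higher and 7 lower of 15, or 7 and 7 adjusted over the list alone (median 0.16, mean −0.39, test downward, adjusted p = 0.979). The lectin gene Clec10a fell 9.57-fold and Irf8, a factor of dendritic cell development, rose 3.08-fold.

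The other lists were not called by camera at the preset correlation in this comparison, where fry, which does not set a list against other genes, called 27 of 30 lists in all. The MHC class II pathway had 5 higher and 6 lower of 13, or 6 and 6 adjusted over the list alone (median −0.06, adjusted p = 0.652), with H2-DMa down 3.67-fold. Endocytosis and scavenger receptors had 11 higher and 11 lower of 24, or 11 and 12 adjusted over the list alone (median −0.06, mean 0.43, test upward, adjusted p = 0.874). Within that list the scavenger receptor Marco rose 181-fold (log2 7.50, SE 0.045) and Cav1, which encodes caveolin, 60.4-fold. Lysosome genes had 8 higher and 18 lower of 30 (median −0.24, adjusted p = 0.129), and cholesterol efflux genes 4 and 8 of 14, or 4 and 9 adjusted over the list alone (median −0.53, adjusted p = 0.157), with the lipid transporter Abcg1 down 5.03-fold. Ribosomal protein genes had 8 higher and 9 lower of 23, or 10 and 9 adjusted over the list alone (median 0.14, mean −0.04, test downward, adjusted p = 0.915, median −0.08 under quantile normalization). B cell markers had 3 higher and 2 lower of 8 (median 0.28, mean −0.23, test upward, adjusted p = 0.652) and T and NK cell markers 6 and 2 of 11 (median 0.45, mean −0.20, test upward, adjusted p = 0.707). Mast cell and basophil markers had 3 higher and 2 lower of 9 (median 0.13, adjusted p = 0.707), with the histidine decarboxylase gene Hdc up 11.7-fold and Il1rl1, the receptor for interleukin 33, down 9.52-fold. Eosinophil markers had 0 higher and 6 lower of 7 (median −0.49, adjusted p = 0.0671, and 0.0358 without nanoparticle replicate 1), plasmacytoid dendritic cell markers 2 and 3 of 7 (median −0.12, adjusted p = 0.839), erythroid markers 2 and 2 of 5 (median −0.05, mean −0.01, test upward, adjusted p = 0.979), and stroma and osteoclast markers 4 and 1 of 8 (median 0.43, adjusted p = 0.129).

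In all, 13503 genes differed between nanoparticles and PBS, 6374 higher and 7129 lower (limma, Benjamini-Hochberg; 6067 and 5987 with median scaling), and 4756 by at least 2-fold. Where a list is given 1 pair of counts, here and for LPS or nanoparticles in the later comparisons, the counts adjusted over the list alone were the same. With slide as a block 12503 genes were called, and 12788 between the 3 PBS arrays and 1 nanoparticle array of slide 1. All 81 genes named for this comparison, by the rule or after their values were seen, were called with and without the block. The block gave medians of 5.53 for cytokines, 2.25 for NF-κB, 1.21 for interferon response and 1.80 for cholesterol synthesis. With an estimated correlation 10 of the 16 lists called were called again: cytokines, chemokines, costimulation, NF-κB, interferon response, effectors, oxidative stress, endoplasmic reticulum stress, cholesterol synthesis and cell cycle. Tlr4 was at 0.12 on the log2 scale (SE 0.045, adjusted p = 0.0388), a call lost without any 1 of PBS replicates 1 to 3 (adjusted p = 0.0713, 0.097 and 0.0778), nanoparticle replicates 1 to 3 (0.0525, 0.0524 and 0.121) or unparticulate γ-PGA replicate 2 (0.0559), and under 7 other settings (0.072 to 0.355).

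**Figure D1:**
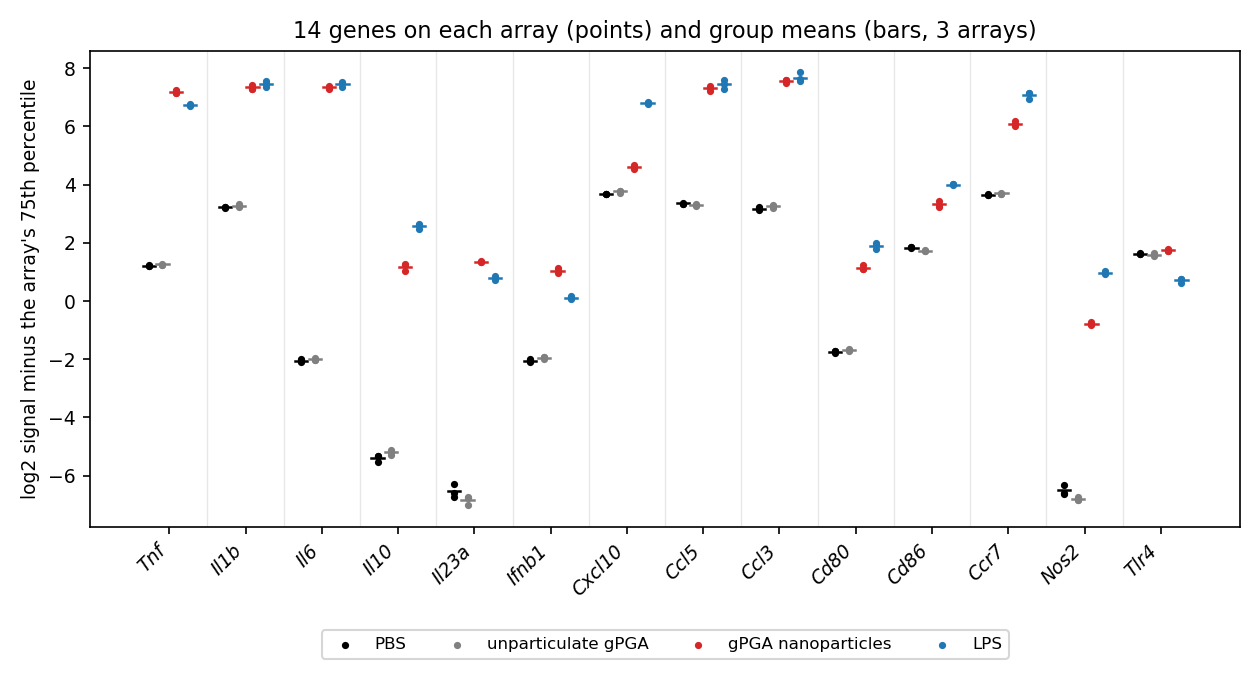
Signal of 14 genes fixed in advance on each of the 12 arrays (points) with group means (bars), as log2 signal minus the array's 75th percentile. The PBS and unparticulate γ-PGA arrays lie together, and nanoparticles raised Tnf by 5.96 and LPS by 5.51.

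LPS raised the inflammatory genes and the whole interferon list. All 36 interferon response genes rose, each by at least 2-fold (median 2.86, adjusted p = 6.63e-18, slide-block median 2.95). Rsad2 rose 42.7-fold (log2 5.42, SE 0.048, adjusted p = 4.52e-13), the exonuclease Isg20 31.3-fold, Irf7, a transcription factor that drives interferon genes, 22.8-fold and Cxcl10 8.85-fold (log2 3.15, SE 0.042). Ifnb1 rose 4.50-fold (log2 2.17, SE 0.052). All 13 genes of the MHC class I pathway rose (median 1.27, adjusted p = 1.39e-05), including Tap1 by 5.22-fold and the immunoproteasome subunit Psmb9 by 3.52-fold. Tnf rose 45.7-fold (log2 5.51, SE 0.035), Il6 at least 727-fold, Il1b at least 18.9-fold, Il10 at least 134-fold, Il23a at least 38.9-fold, Ccl3 at least 22.5-fold, Ccl5 at least 17.0-fold and Nos2 at least 44.4-fold. All 19 cytokines rose (median 5.51, or 4.75 at the bounds, adjusted p = 2.79e-11), as did 19 of 20 chemokines (median 3.25, adjusted p = 4.88e-10) and all 24 NF-κB and feedback genes (median 2.54, adjusted p = 4.94e-12).

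Maturation genes rose after LPS too, with 17 of 18 costimulation and maturation genes higher and 1 lower (median 2.93, or 2.63 at the bounds, adjusted p = 1.14e-08). Cd80 rose 12.5-fold (log2 3.65, SE 0.064), Cd86 4.50-fold, Ccr7 10.8-fold and Fscn1, the actin-bundling protein of mature dendritic cells, 14.3-fold. Tlr4 itself fell 1.88-fold (log2 −0.91, SE 0.045, adjusted p = 2.64e-08). Effectors had 21 of 22 genes higher and 1 lower (median 3.27, adjusted p = 4.84e-10), and endoplasmic reticulum and amino acid stress genes 17 higher and 5 lower of 23 (median 0.87, adjusted p = 0.00124), with Hspa1a up 68.8-fold. Nts, which encodes the peptide neurotensin, rose at least 1450-fold. Cell cycle genes fell, 26 of 29 with 1 higher (median −1.36, adjusted p = 2.15e-08), including Ccnb2, which encodes cyclin B2, by 4.72-fold and Birc5 by 4.56-fold. Cholesterol synthesis genes were split, 9 higher and 9 lower of 22 (median 0.12, mean −0.15, test downward, adjusted p = 0.894). The sterol reductase Dhcr7 fell 6.57-fold (log2 −2.72, SE 0.067), and Hsd17b7 rose 2.50-fold.

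Several lists passed after LPS only at the preset correlation. They were Toll-like receptors and adaptors (19 higher and 5 lower of 25, median 0.79, adjusted p = 0.000886, and adjusted p = 0.11 with an estimated correlation) and cell death (14 and 7 of 22, median 1.15, adjusted p = 0.00706, and adjusted p = 0.0868 with an estimated correlation). Oxidative stress genes had 17 higher and 3 lower of 21, or 18 and 3 adjusted over the list alone (median 0.62, adjusted p = 0.000161, and adjusted p = 0.0868 with an estimated correlation). Glycolysis and hypoxia genes had 19 higher and 4 lower of 23 (median 0.64, adjusted p = 0.000256, and adjusted p = 0.174 with an estimated correlation), with the glycolytic regulator Pfkfb3 up 7.44-fold. Lysosome genes had 7 higher and 21 lower of 30 (median −0.38, adjusted p = 0.0371, adjusted p = 0.176 with an estimated correlation, and 0.0625 with slide as a block at a median of −0.37), with the acid lipase Lipa down 3.24-fold.

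Cell type markers were not called by camera at the preset correlation after LPS. Macrophage markers had 4 higher and 9 lower of 13 (median −1.22, or −0.93 at the bounds, adjusted p = 0.12), with Cd5l, a macrophage-secreted protein, down 10.3-fold, and neutrophil markers 4 and 10 of 14 (median −0.32, adjusted p = 0.169, and 0.0369 under quantile normalization), with Retnlg down 5.31-fold. Dendritic cell markers had 6 higher and 7 lower of 15 (median −0.50, adjusted p = 0.894), with Clec10a down 14.4-fold and Irf8 up 4.46-fold. The lists not given for LPS were not called by camera either (adjusted p from 0.167 to 0.894), though fry called 28 of 30 lists in all. In this comparison 14086 genes differed, 6723 higher and 7363 lower, and 5631 by at least 2-fold. More genes were higher than lower with median scaling (6649 and 6249) and the value table (6360 and 5825). LPS and PBS shared no slide, and with slide as a block 11789 genes were called, including all 69 of the genes named for this comparison and called without it. With an estimated correlation 9 of 14 lists were called again: cytokines, chemokines, costimulation, MHC class I, NF-κB, interferon response, effectors, endoplasmic reticulum stress and cell cycle.

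After unparticulate γ-PGA, at the dose of the particles, none of the 14 fixed genes analysed passed the test against PBS (limma, adjusted p from 0.072 to 0.747). Tnf differed from PBS by 0.04 on the log2 scale (95% interval −0.04 to 0.12, adjusted p = 0.581), Il6 by 0.06 (−0.05 to 0.17), Il1b by 0.04 (−0.10 to 0.18), Cd80 by 0.07 (−0.08 to 0.21), Cd86 by −0.10 (−0.21 to 0.01) and Ccr7 by 0.05 (−0.08 to 0.18). Ifnb1 differed by 0.11, Cxcl10 by 0.10, Ccl3 by 0.08, Ccl5 by −0.05 and Tlr4 by −0.03, with adjusted p from 0.204 to 0.747. These groups shared no slide, and with slide as a block none of the 14 passed either (adjusted p from 0.284 to 0.997), but Cd80 stood at −0.17 (SE 0.131), Cd86 at 0.12 (SE 0.074), Ccr7 at −0.09 (SE 0.135), Ccl5 at 0.20 and Tlr4 at 0.17, all with the other sign. Ifnb1 stood at 0.23, Cxcl10 at 0.25, Ccl3 at 0.33, Il6 at 0.17 and Il1b at 0.14, so the direction of small differences is not settled. Il10, Il23a and Nos2 were not well above background in either group. Of 19 cytokines 1 was higher and 1 lower, or 2 and 1 adjusted over the list alone, and of 20 chemokines 2 were higher, or 3 with 1 lower. The cytokine gene Tnfsf15 was at least 1.6-fold higher (adjusted p = 0.00933), and Csf2, called lower, was not well above background in either group. The chemokine gene Ccl12 was higher by 0.25 (SE 0.056, adjusted p = 0.0352) and the monocyte attractant Ccl2 by 0.16 (SE 0.031, adjusted p = 0.0232). Among cell death genes the DNA sensor Aim2 was at least 1.76-fold lower (adjusted p = 0.032). Marco was higher by 0.40 (SE 0.045, adjusted p = 0.00473) and the cell cycle inhibitor Cdkn1a by 0.28 (SE 0.034, adjusted p = 0.00559), Kank1 was at least 3.26-fold higher (adjusted p = 0.00912), and the zinc finger gene Zfp317 was lower at −1.78 (SE 0.150, adjusted p = 0.00183), as was Ciita, the activator of MHC class II genes, at −0.36 (SE 0.049, adjusted p = 0.0077). With slide as a block Marco stood at 0.40 (adjusted p = 0.217), Cdkn1a at 0.16 (0.355), Kank1 at 1.38 (0.397), Zfp317 at −1.47 (0.135) and Ciita at −0.25 (0.396). Marco's call was also lost with median scaling (0.187) and the value table (0.368), and Kank1's with normexp (0.233).

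Of the genes called after unparticulate γ-PGA, 5 lost their calls with slide as a block as follows, Tnfsf15 at 0.72 (adjusted p = 0.296), Csf2 at −0.19 (0.59), Ccl12 at 0.22 (0.534), Ccl2 at 0.23 (0.245) and Aim2 at −1.10 (0.518), and with normexp (0.104 to 0.866). Tnfsf15, Csf2, Ccl12 and Ccl2 also lost them with median scaling (0.0527 to 0.883) and the value table (0.0832 to 0.999), Csf2 under quantile normalization (0.132), and Ccl12, Ccl2 and Aim2 with no filter on dim probes (0.0734 to 0.109). Without PBS replicates 1, 2 and 3 the adjusted p of Ccl12 was 0.07, 0.121 and 0.102, of Ccl2 0.0639, 0.0748 and 0.0826, and of Aim2 0.0579, 0.0917 and 0.102. Without unparticulate γ-PGA replicates 1, 2 and 3 that of Ccl2 was 0.0589, 0.0748 and 0.0962 and of Csf2 0.056, 0.057 and 0.0662. Ccl12 was at 0.0723 and 0.11 without replicates 1 and 3 of that group, at 0.0514 without nanoparticle replicate 2 and at 0.0512 without LPS replicate 1, and Aim2 at 0.0645 and 0.086 without unparticulate γ-PGA replicates 2 and 3. Ccl12 and Ccl2 further lost their calls with outlier-marked spots kept (0.0515 and 0.066) and with the replicate block (0.0513 and 0.0632).

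Without the block 976 genes differed between unparticulate γ-PGA and PBS, 622 higher and 354 lower, and 174 by at least 2-fold. These groups shared no slide. With slide as a block 20 genes were called, 7 higher and 13 lower (2470 at an unadjusted p under 0.05). Of these 20, 2 were among the 976 with the same direction in both fits. The split of 622 and 354 became 109 and 162 with normexp and 464 and 425 under quantile normalization. Other settings gave 178 (value table), 254 (median scaling), 271 (normexp), 308 (no filter), 393 (replicate block), 588 (outlier-marked spots kept) and 3596 genes (only these 6 arrays). The count was 309, 224 and 264 without PBS replicates 1, 2 and 3, 278, 165 and 147 without unparticulate γ-PGA replicates 1, 2 and 3, and 1500 without LPS replicate 3. By camera at the preset correlation 1 list was called, where fry called 7 and camera with no filter on dim probes 4. This was the interferon response list, with 10 genes higher and 1 lower of 36, or 16 and 1 adjusted over the list alone (median 0.11, adjusted p = 0.000178, and adjusted p = 0.125 with an estimated correlation). With slide as a block its median was 0.16 (adjusted p = 8.5e-05), and 0 of its members were called by limma. The medians of the other lists lay between −0.03 and 0.19.

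**Figure D2:**
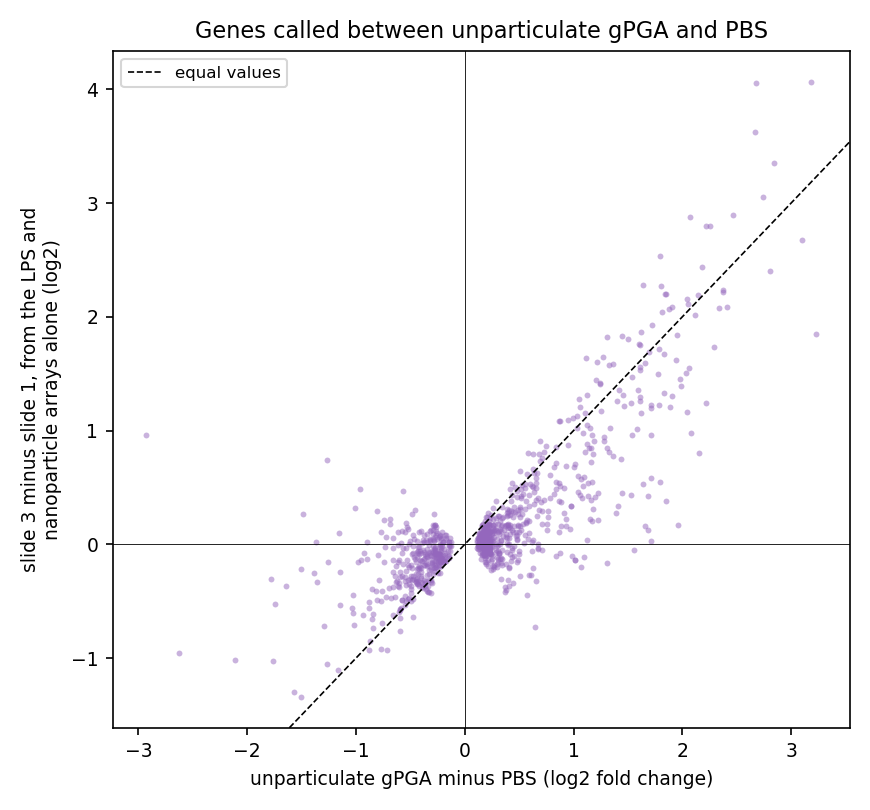
Genes called between unparticulate γ-PGA and PBS, by their log2 fold change (horizontal axis) and by the offset between slide 3 and slide 1 estimated from the LPS and nanoparticle arrays alone (vertical axis, log2). Of 952 genes 711 have the same sign on both axes (61.8% over all genes), and the slope is 0.659.

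**Figure D3:**
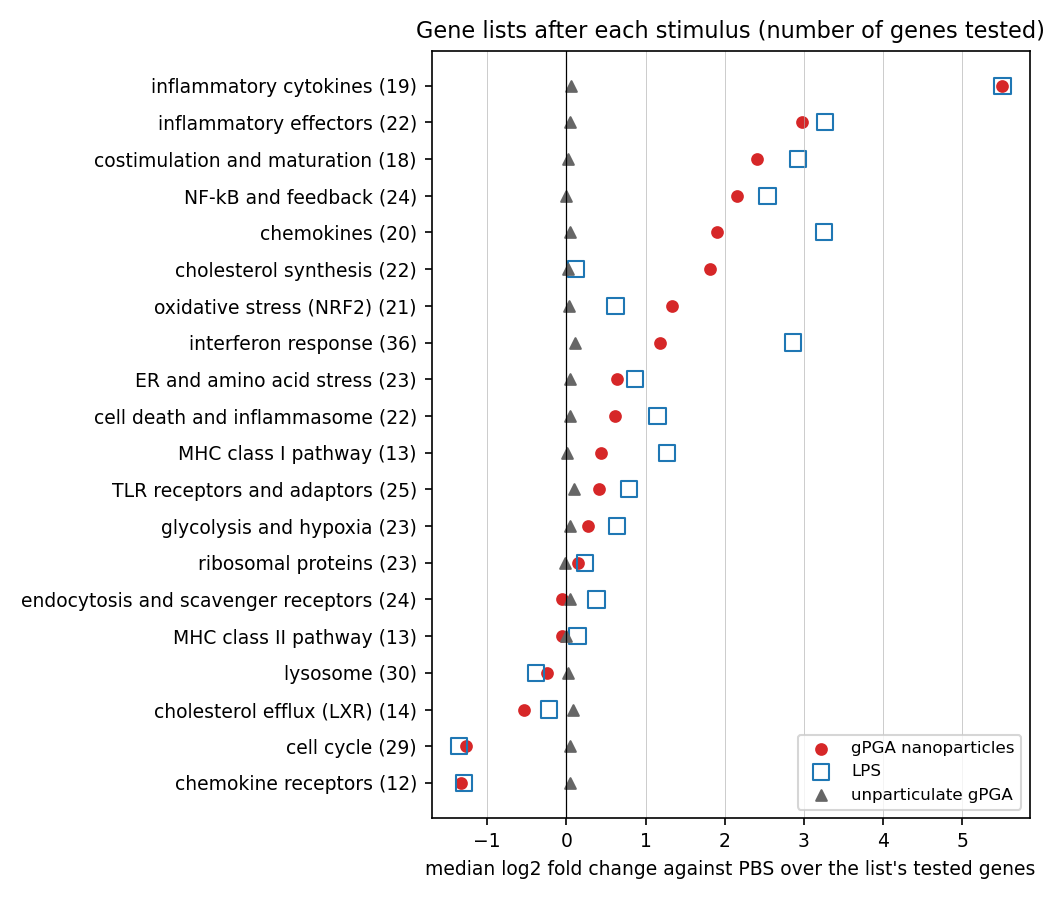
Median log2 fold change against PBS over the tested genes of each response list, for nanoparticles, LPS and unparticulate γ-PGA. Unparticulate γ-PGA lies near 0 for every list, and nanoparticles and LPS part most at cholesterol synthesis (1.81 and 0.12) and the interferon response (1.18 and 2.86).

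Set directly against LPS, nanoparticles gave lower genes of the interferon response list, except Ifnb1, and higher cholesterol synthesis genes. Of 36 interferon response genes 35 were lower and 1 higher, 33 of them lower by at least 2-fold (median −1.88, adjusted p = 6.33e-25). The one higher was Ifnb1, which encodes interferon beta itself, by 0.93 on the log2 scale (SE 0.052, adjusted p = 2.87e-07, and 0.89 with slide as a block), a gene named here after its values were seen. Isg20 was 6.98-fold lower (log2 −2.80, SE 0.046, adjusted p = 1.44e-10), Irf7 5.85-fold, Ifit3 5.49-fold and Oas3 5.13-fold. All 22 cholesterol synthesis genes were higher, 19 by at least 2-fold (median 1.96, adjusted p = 3e-17). Lss, the lanosterol synthase, was 7.27-fold higher (log2 2.86, SE 0.063, adjusted p = 5.41e-10), Hsd17b7 5.10-fold, Mvd 4.76-fold and Dhcr7 4.64-fold. Between the arrays of slide 2 the interferon median was −1.91 and the cholesterol median 1.94.

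The MHC class I pathway, costimulation and NF-κB lists were lower after nanoparticles than after LPS. In the MHC class I pathway 0 were higher and 11 lower of 13, or 12 lower adjusted over the list alone (median −0.86, −0.88 within slide 2, adjusted p = 6.22e-07), with Tap1 3.33-fold and Psmb9 2.95-fold lower. Of 18 costimulation genes 13 were lower (median −0.46, −0.52 within slide 2, adjusted p = 4.18e-05), with Il15ra, the interleukin 15 receptor, 2.13-fold and Cd80 1.68-fold lower. Of 24 NF-κB and feedback genes 20 were lower and 1 higher, or 21 and 1 adjusted over the list alone (median −0.43, −0.46 within slide 2, adjusted p = 6.22e-07), with the phosphatase gene Dusp2 2.80-fold lower. These 5 lists held with an estimated correlation, at adjusted p from 0.000434 to 0.0256. Oxidative stress genes were higher, 14 of 21 with 1 lower (median 0.50, also within slide 2, adjusted p = 1.85e-05, and adjusted p = 0.0711 with an estimated correlation). Nqo1 was 4.32-fold, the malic enzyme Me1 2.91-fold and Gclm 2.38-fold higher (Gclm from 2 nanoparticle arrays). The glutathione transferase genes Gsta1 and Gsta2 were at least 13.9-fold and at least 6.00-fold higher.

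Of 19 cytokines 6 were higher and 7 lower after nanoparticles than after LPS (median −0.12, mean 0.01, test downward, adjusted p = 0.521). Il6 and Il1b among them, and Ccl3 and Ccl5 among the chemokines, were saturated on all 3 arrays of both groups, so the arrays cannot show whether they differed. Csf2 was 6.09-fold and Csf3, which encodes G-CSF, 3.29-fold higher after nanoparticles, and Il23a 1.47-fold (log2 0.56, SE 0.106, adjusted p = 0.00158). Il10 was 2.63-fold (log2 −1.40, SE 0.083) and Il18 2.67-fold lower. Of 20 chemokines 4 were higher and 8 lower (median −0.16, adjusted p = 0.0341, adjusted p = 0.336 with an estimated correlation, and 0.154 under quantile normalization). Of these 20, Cxcl5 was 6.24-fold higher, while Cxcl9 and Cxcl10, both inducible by interferon, were 4.88-fold and 4.59-fold lower. Ppbp, a platelet chemokine outside the list, was 8.46-fold higher (log2 3.08, SE 0.037). Effectors had 4 higher and 14 lower of 22 (median −0.48, or −0.41 at the bounds, adjusted p = 0.00877, and adjusted p = 0.146 with an estimated correlation). Nos2 was 3.38-fold lower, and F3, the coagulation tissue factor, 2.87-fold higher. The greatest differences downward also held Slfn4 (13.3-fold), Ly6a (12.1-fold) and the IgG receptor Fcgr1 (8.67-fold), and upward Cyp26b1, a retinoic acid hydroxylase (8.87-fold).

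Further lists differed between the stimuli at the preset correlation only. Those lower after nanoparticles were cell death genes (4 higher and 14 lower of 22, or 4 and 15 adjusted over the list alone, median −0.32, adjusted p = 0.00215, and adjusted p = 0.0711 with an estimated correlation) and glycolysis and hypoxia (4 and 13 of 23, median −0.25, adjusted p = 0.00328, adjusted p = 0.228 with an estimated correlation, and 0.0541 under quantile normalization), with Vegfa 3.90-fold lower. Toll-like receptors and adaptors had 3 higher and 16 lower of 25 (median −0.23, adjusted p = 0.0145, adjusted p = 0.203 with an estimated correlation, and 0.0825 under quantile normalization), though Tlr4 was 2.04-fold higher (log2 1.03, SE 0.045). Endocytosis receptors had 5 higher and 14 lower of 24, or 6 and 14 adjusted over the list alone (median −0.24, adjusted p = 0.0309, adjusted p = 0.117 with an estimated correlation, and 0.186 under quantile normalization). Cholesterol efflux genes had 4 and 9 of 14, or 4 and 10 adjusted over the list alone (median −0.46, adjusted p = 0.0373, adjusted p = 0.14 with an estimated correlation, and 0.0984 under quantile normalization), with the lipid exporter Abca1 2.18-fold lower. Lysosome genes were higher, 18 of 30 with 5 lower (median 0.17, adjusted p = 0.0205, and adjusted p = 0.146 with an estimated correlation), with Lipa 2.54-fold higher.

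Cell type markers were lower in 4 lists after nanoparticles than after LPS. Macrophage markers had 1 higher and 6 lower of 13, or 1 and 7 adjusted over the list alone (median −0.19, adjusted p = 0.0255, adjusted p = 0.203 with an estimated correlation, and 0.103 under quantile normalization). Neutrophil markers had 2 and 8 of 14, or 2 and 9 adjusted over the list alone (median −0.32, adjusted p = 0.03, adjusted p = 0.302 with an estimated correlation, 0.0599 under quantile normalization, and 0.0612 without nanoparticle replicate 1). B cell markers had 0 and 5 of 8 (median −0.46, adjusted p = 0.0205, and adjusted p = 0.0875 with an estimated correlation), and eosinophil markers 0 and 5 of 7 (median −0.64, adjusted p = 0.0134, and adjusted p = 0.0715 with an estimated correlation), with the eosinophil peroxidase gene Epx 2.33-fold lower. Cell cycle genes (14 higher and 10 lower of 29, or 15 and 10 adjusted over the list alone, median 0.10, adjusted p = 0.373) and dendritic cell markers (5 and 4 of 15, median 0.06, adjusted p = 0.898) were not called, nor were the lists not given (adjusted p from 0.358 to 0.942). In all 9250 genes differed, 4719 higher and 4531 lower, and 1271 by at least 2-fold, 426 higher and 845 lower. The count was 6126 with normexp and 5070 with the value table. Fewer genes were higher than lower with the value table (2079 and 2991), median scaling (2946 and 3272), outlier-marked spots kept (3855 and 4772) and only these 6 arrays (3728 and 3757). With slide as a block 8787 genes were called and within slide 2 4682, and all 68 genes named for this comparison kept their call with the block.

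**Figure D4:**
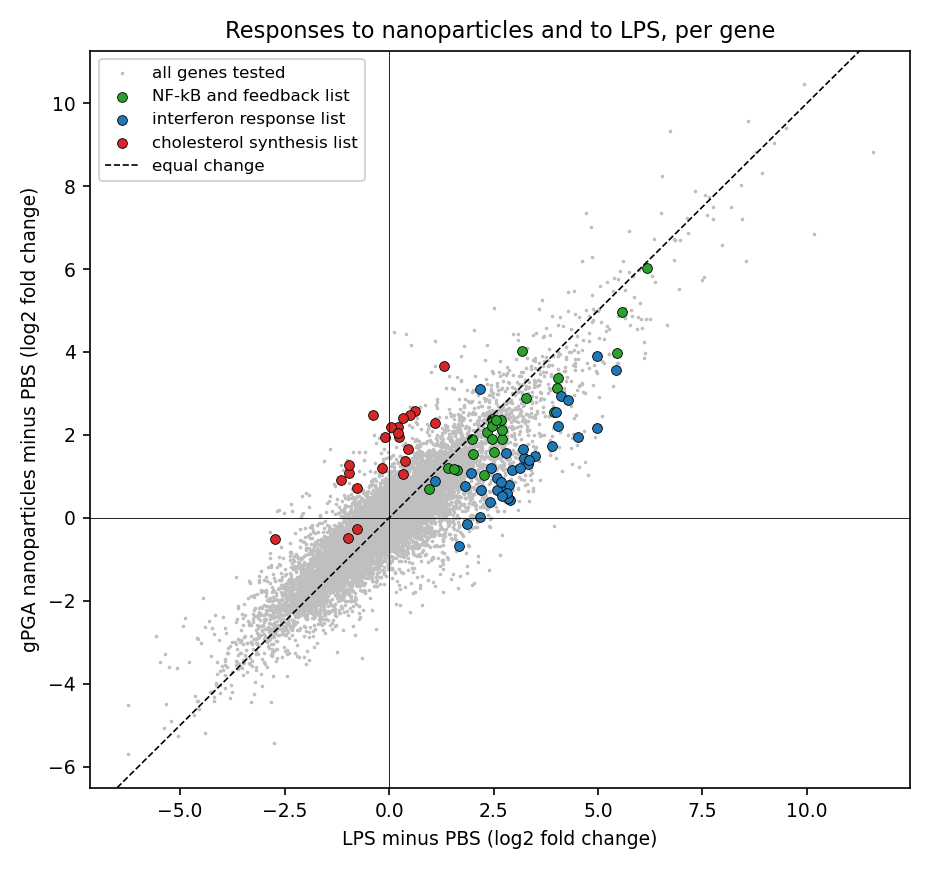
Log2 fold change against PBS of each gene tested, after LPS (horizontal axis) and after nanoparticles (vertical axis), with 3 lists coloured. The 36 interferon response genes lie mostly below the line of equal change (median difference −1.88), and the 22 cholesterol synthesis genes lie above it (median difference 1.96).

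The responses to nanoparticles and to LPS were correlated across genes, though they share the 3 PBS arrays. The covariance of the log2 fold changes was 1.29 (1.35 with slide as a block, 0.61 with normexp and 0.802 with no filter on dim probes), against 0.0177 simulated for unchanged groups, and the correlation 0.893 against 0.499 simulated. At least 2-fold rises numbered 1961 after nanoparticles and 2523 after LPS with 1589 shared, where independent lists would share 269. Falls numbered 2795 and 3108 with 2261 shared, against 472. The counts for independent lists ignore the shared PBS arrays, so part of the excess overlap may come from them. No split of the PBS arrays is given here. The simulated covariance of 0.0177 already includes the sharing, so the covariance of 1.29 argues against shared controls as its main source. Of the 1589 shared rises LPS was higher in 727 and nanoparticles in 293, and 569 did not differ. Opposite changes of at least 2-fold were seen in 22 genes. The covariance with the unparticulate γ-PGA changes was 0.027 for nanoparticles and 0.058 for LPS, and 0.11 and 0.206 with slide as a block.

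The particles were then set against the unparticulate polymer at the same dose. Il1a was 445-fold higher (log2 8.80), Cxcl1 916-fold (log2 9.84, SE 0.075, adjusted p = 2.69e-13), Il6 at least 643-fold, Ptgs2 at least 1280-fold and Marco 137-fold (log2 7.10, SE 0.045). All 19 cytokines (median 5.00, adjusted p = 4.35e-12) and all 24 NF-κB genes (median 2.25, or 2.19 at the bounds, adjusted p = 2.02e-12) were higher, as were 34 of 36 interferon response genes with 1 lower (median 1.02, adjusted p = 7.74e-12). Cholesterol synthesis genes had 19 higher and 3 lower of 22 (median 1.93, adjusted p = 1.88e-07), with Hsd17b7 13.2-fold and Hmgcs1 6.43-fold higher, and cell cycle genes 1 higher and 27 lower of 29 (median −1.27, adjusted p = 1.05e-08), with Ccnd1 5.35-fold lower. Cyp2s1, a cytochrome P450, was 41.4-fold lower (log2 −5.37, SE 0.098). In all 13972 genes differed, 6250 higher and 7722 lower, 5254 by at least 2-fold and 11217 with slide as a block. More genes were higher than lower with median scaling (6645 and 5902), the value table (5983 and 5676) and no filter on dim probes (10990 and 8099). The groups shared no slide.

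Against the unparticulate polymer, LPS gave Nts at least 1900-fold, Il6 at least 698-fold, Cxcl1 467-fold and Rsad2 40.0-fold higher (log2 5.32, SE 0.048, adjusted p = 5.54e-13). All 36 interferon response genes (median 2.77, 2.76 within slide 3, adjusted p = 8.01e-19) and all 13 MHC class I genes (median 1.32, adjusted p = 5.59e-06) were higher. Cholesterol synthesis genes had 10 higher and 9 lower of 22 (median 0.15, mean −0.14, test upward, adjusted p = 0.973), and Dhcr7 was 6.63-fold lower. In all 14023 genes differed, 6352 higher and 7671 lower, 5712 by at least 2-fold, 12846 with slide as a block and 13714 within slide 3, which held 1 LPS array. More genes were higher than lower with normexp (6139 and 5684), median scaling (6856 and 5873) and the value table (6573 and 5468). Scaling moved the median of all genes by 0.122 (normexp), 0.147 (median scaling) and 0.129 (value table) for nanoparticles against the unparticulate polymer, and by 0.201, 0.159 and 0.174 for LPS against it. With an estimated correlation 10 of 17 lists called for nanoparticles and 9 of 13 for LPS were called again in these comparisons.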

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

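The regroupings of the arrays were planned before the results were seen, and the tests of slide offsets, of a response reduced by 1 factor, of damage to an array and of a brighter array were chosen only after them. Negative control spots, which should bind no mouse transcript, stood out in data that no comparison uses: on nanoparticle replicate 1, 11 of them were well above background, against 0, 2 and 5 on the PBS arrays. All 11 lay in a part of that array with surface damage or dirt as a candidate cause, which holds 52 of its 153 negative controls (Fisher's exact test, two-sided p = 3.24e-06). Whether the array was brighter as a whole is not decided. Outside that part 0.344% of its spots were more than 4-fold above the other nanoparticle arrays, below the 1.14% of LPS replicate 3 against its own group. Each array's median difference was removed before this count, which takes out an even rise in brightness. The median signal was 36.9 on this array, against 26.7 and 27.6 on nanoparticle replicates 2 and 3. No biological explanation was tested. With that part masked 13493 genes were called against PBS and without the whole array 13190, against 13503.

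The genes called between unparticulate γ-PGA and PBS compare arrays of slide 3 with arrays of slide 1. The offset between these slides, estimated from LPS and nanoparticle arrays alone, had a slope of 0.977 (SE 0.011, r 0.548) on the fold changes of all 18095 genes and of 0.659 (SE 0.016) on those of 952 called genes, and the same sign for 61.8% and 74.7% of them. The offset is therefore a candidate cause of the difference. Its median size on the log2 scale was 0.164 against fold changes of 0.092 over all genes and 0.159 against 0.396 over the called ones. Over the 172 called genes with a change of at least 2-fold it was 1.05 against 1.51. There the slope was 0.63 (SE 0.041) and 93.0% had the same sign. The offset thus followed much of the larger changes, and its exact share stays open. The calls lost with slide as a block (20 in place of 976) come partly with a larger SE, since the block raised its median from 0.0722 to 0.147. Marco, whose offset was −0.003, lost its call at the same 0.40. The fold changes moved too. With and without the block they correlated at 0.0185 over all genes, against 0.929 to 0.978 in the other comparisons. The block takes the slide shift from the same LPS and nanoparticle arrays, so it is not a separate check. The offset rests on 1 LPS array and 1 nanoparticle array at the outer slides, and an effect of the unparticulate polymer stays open.

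Interferon response genes were lower and cholesterol synthesis genes higher after nanoparticles than after LPS, and a slide offset is argued against by slide 2 alone, where the medians were −1.91 and 1.94. An LPS response reduced by 1 factor is argued against by the median ratio of the nanoparticle to the LPS response, 0.419 for 36 interferon genes and 0.835 for 23 NF-κB genes. Their difference of −0.415 had a permutation p of 1e-05 (two-sided), the smallest that 100000 resamples can give. The permutation moved genes between the lists, so its p treats genes as independent and does not measure the spread between arrays. A response reduced by 1 factor is argued against for cholesterol synthesis too, since 19 of 22 members stood above both PBS and LPS after nanoparticles. A signal of the particles other than that of LPS may be the cause, as a hypothesis formed on these data that was not itself tested. A smaller amount of LPS whose genes respond unequally to dose stays open for both parts, since no dose or time series was run. For cholesterol synthesis it would need a rise at a smaller amount that is lost or smaller at 1 µg/ml. Ifnb1 itself was, however, higher after nanoparticles than after LPS by 0.93 (log2).

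The 10 splits of the 6 arrays of a comparison are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 13503, 14086, 976, 9250, 13972 and 14023, where the highest other split gave 1, 0, 1, 58, 0 and 4. Of 100 regroupings of the 12 arrays into 4 groups 1, the real one, gave 15732 genes that differed among the groups and the highest other gave 3325. For this overall count a random grouping of the arrays is argued against. The regroupings decide no single comparison, and they do not separate treatment from slide, since groups and slides largely coincide.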

How the results depend on the processing

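Masking the part of nanoparticle replicate 1 with many bright or outlying spots, and the slide block and the fit without that array for the gene lists, were chosen only after the results were seen. Of 300 results for named genes, leaving out arrays aside, 3446 of 3541 values stayed on their side of the threshold, 94 lost the call and 1 reversed. Of the 3446, 21 turned sign while called in neither fit, all fixed genes in unparticulate γ-PGA against PBS. All lost calls were in unparticulate γ-PGA against PBS or of Tlr4 in nanoparticles against PBS. Irf7 reversed in unparticulate γ-PGA against PBS with slide as a block, at −0.10. Of 1260 values for lists 1121 stayed on their side, 57 of them with the direction of the test turned but called in neither, 47 lost the call, 80 gained it and 12 reversed. Unless stated, the cause was not tested.

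For unparticulate γ-PGA against PBS the count of 976 became 271 with normexp, 254 with median scaling, 178 with the value table, 308 with no filter on dim probes, 588 with outlier-marked spots kept, 3596 with only the 6 arrays and 20 with slide as a block. Nanoparticles against LPS gave 6126 with normexp and 5070 with the value table. The covariance of both responses was 0.61 with normexp and 0.802 with no filter, which adds genes near background. With a 2-fold minimum the counts were 4756, 5631, 174, 1271, 5254 and 5712, and 7330 for any difference, by construction lower. Leaving out 1 array gave 12817 to 13774 for nanoparticles and 13485 to 14277 for LPS against PBS, 147 to 1500 for unparticulate γ-PGA, 8631 to 9242 for nanoparticles against LPS, 13278 to 14241 and 13357 to 14221 against unparticulate γ-PGA, 15283 to 15898 for any difference and 1.27 to 1.30 for the covariance. Lists called without nanoparticle replicate 1 were 18, 14, 1, 17, 17 and 13.

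With an estimated correlation 10, 9, 0, 5, 10 and 9 lists were called, where the preset gave 16, 14, 1, 18, 17 and 13, and with fry, which does not set a list against other genes, 27, 28, 7, 28, 29 and 28. Of the 0 lists in unparticulate γ-PGA against PBS, camera with the preset correlation called 1. No filter gave 4 lists there, and quantile normalization 11 for nanoparticles against LPS. The direction of fry opposed camera's for mast cell markers in nanoparticles against PBS (median 0.13), plasmacytoid (0.17) and erythroid markers (0.26) in LPS against PBS, erythroid markers in nanoparticles against LPS (−0.30), dendritic cell (0.27), T and NK cell (0.32) and mast cell markers (−0.01) in nanoparticles against unparticulate γ-PGA, and cholesterol synthesis (0.15) and plasmacytoid markers (0.16) in LPS against it. Quantile normalization reversed the ribosomal protein median in LPS against PBS (−0.10) and in nanoparticles and LPS against unparticulate γ-PGA (−0.09 in both).

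No pairing of the arrays by replicate number was seen. Deviations from group means correlated at a median of 0.006 over 18 same-numbered pairs (−0.167 to 0.07) and −0.001 over 36 others (−0.084 to 0.153). Of 12 arrays 5 correlated best with one of their own number, a count not set against a chance level. A pairing is not excluded, since slide shifts within the nanoparticle and LPS groups also enter these deviations. With the replicate block unparticulate γ-PGA against PBS gave 393 genes. The arrays limit what dim genes can show, since 50.9% to 59.6% of spots were well above background.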

Other observations

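The tests of single genes here were chosen after their values were seen. Some genes moved in opposite directions after the stimuli, 22 by at least 2-fold each way, and 19 of these were lower after nanoparticles and higher after LPS. Fcgr1, the high-affinity IgG receptor, stood at −1.41 after nanoparticles and 1.71 after LPS (log2 against PBS, SE 0.041, limma adjusted p = 6.06e-10 and 1.17e-10, n = 3 arrays per group). Ly6a, an interferon-inducible surface antigen, stood at −1.56 and 2.03 (SE 0.160), with 2 of 3 nanoparticle arrays well above background, and with slide as a block at −1.98 and 1.42. The NK receptor gene Klrk1 stood at −1.54 and 1.04 (SE 0.069). Siglec1, the sialic acid receptor of macrophages, stood at −1.36 and 1.54 (SE 0.202), also with 2 of 3 nanoparticle arrays well above background. With slide as a block it stood at −1.78 and 0.89. The platelet chemokine gene Ppbp ran the other way, at 1.66 and −1.42 (SE 0.037).

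Of 240 genes at least 2-fold higher after LPS, not called higher after nanoparticles and different between both, 150 had a symbol and 3 were in the interferon response list. Over all genes with a symbol 0.466 of those 150 would be by chance, but all 36 list members rose at least 2-fold after LPS. The set held 240 of the 2523 genes with such a rise and 3 of these 36, so no excess is shown. Of the 70 genes in the reverse position 51 had a symbol and 8 were in the cholesterol synthesis list of 22. Over all genes with a symbol 0.0969 of those 51 would be by chance. But 19 of the 22 members stood above both PBS and LPS after nanoparticles, so this base is too low. The 8 genes restate that result and are not separate evidence. The set held 70 of the 1961 genes at least 2-fold higher after nanoparticles. Ch25h, which makes 25-hydroxycholesterol, an oxysterol that restrains sterol synthesis, rose by 4.64 after nanoparticles and 6.64 after LPS on the log2 scale (SE 0.044), and was lower after nanoparticles than after LPS at −2 (limma adjusted p = 5.47e-10). The glutathione transferase gene Gsta3 stood at 1.58 after nanoparticles and −0.87 after LPS (SE 0.064).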
